A study of Mus musculus with 24 samples.

How the data were processed

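RNA was measured in 24 libraries of CD8+ T cells from 6 mice, 3 labelled as a conditional knockout of Tcf7 (cKO, mice 1 to 3) and 3 labelled wild type (WT, mice 4 to 6), each sampled at 0, 4, 8 and 24 h. Per the labels' protocols, T cells carrying the OT-I receptor, a transgenic T cell receptor, were taken from spleen and lymph nodes with CD8 microbeads. The cKO mice carried the E8i-cre recombinase transgene and 2 floxed Tcf7 alleles. The WT mice carried the floxed alleles without cre, so the transgene and the deletion cannot be told apart. Cells were sampled at 0 h before plating and then kept on plates coated with antibodies against CD3 and CD28 at 1 ug/mL, with IL2 at 6 ng/mL. For each library 1000 cells were sorted and their RNA was amplified with Smart-seq2, a full-length protocol without molecular identifiers, so intervals and floors cover counting error only.

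Per the submitters' processing notes, reads were handled with STAR and RSEM on the mouse genome mm10, and DESeq2 was also named. Their versions and settings are not given in the sources used here. Per the file headers, each deposited file holds 1 library and gives, for 23420 genes, the expected count, which is RSEM's estimate of the reads of each gene and need not be whole. Per the file headers the same files give TPM, transcript abundance scaled to the same total in every library, and FPKM. TPM was used for levels and for 1 alternative test, and FPKM was not used. Expected counts summed to between 5846265 and 9700397 per library. A ribosomal RNA gene, Rn45s, held 7.39 to 20.6% of them and was kept in the library sizes, with its removal as an alternative. Gene symbols are those of the files. Positions come from the GENCODE annotation of GRCm38, the assembly that mm10 names. Of the 23420 symbols, 23291 were matched to that build.

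Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter on low counts over the 8 groups of 3 libraries, which left 11470. Libraries were scaled by TMM, and 1 robust quasi-likelihood model with a mean for each of the 8 groups gave all 13 comparisons. These were cKO against WT at each of the 4 times, each later time against 0 h in WT and in cKO, and the 3 interactions, which ask whether the genotype difference at a later time differs from that at 0 h. All tests are two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and a gene is called at an adjusted p under 0.05. Fold changes are fitted log2 values with an approximate standard error (SE). This is the absolute log2 fold change divided by the square root of the F statistic of its test, and it is rough where a group is near 0. Levels are mean TPM ± SD over the 3 mice of a group, and replicates are separate animals per the labels. Where a group had no count of a gene, the fold was bounded against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval.

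The main tests, 30 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. In each genotype comparison, in WT at 24 h against 0 h and in the 24 h interaction, the rule names up to 8 genes with the largest increases and 8 with the largest decreases. These genes had to be called, with a mean of at least 10 TPM in the higher group. Except for the interaction, libraries of the 2 groups also had to be without overlap in TMM-scaled CPM, which chance alone gives 10% of genes with 3 against 3. Unnamed gene models were passed over. The other time comparisons name 4 in each direction. Tcf7, Lef1, Cxcr6 and Cd28 are reported in every comparison, and up to 4 called members with the smallest adjusted p are named for a list that is described. Chosen after their values were seen were Car2, Coro2a, Dennd5a, Nt5e, Rcn3 and other genes called at 3 or 4 times wherever they are followed over the times, Ly6c2, Ly6a and Eomes, and the 4 h and 8 h interactions of Dennd5a.

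Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01. Of the 30 lists, 25 had at least 3 tested members and were tested in 10 comparisons, the 4 genotype comparisons, the 3 WT time comparisons and the 3 interactions, and p-values were adjusted over all 250 tests. With the preset correlation 72 tests passed, and in these the median, the mean and the direction of the test had the same sign, while in 47 of the 250 tests they did not all share it. With a correlation estimated from the data, 11 of the 30 genotype calls, 8 of the 31 WT time calls and 0 of the 11 interaction calls passed. The rotation test fry was also run. It asks whether the members move 1 way on balance and does not compare a list with other genes.

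The model and the list test were tested on simulated counts drawn from the real means, spreads and library sizes, with 11301 genes tested. The changed genes were drawn from those with a mean of at least 5 CPM over the groups, so the shares do not cover genes of lower level. At each time 100 genes were changed by each fold. Each gene had 1 spread in all groups, and no structure between mice or libraries was put in. The shares therefore apply to these settings and may not hold in the real libraries. Of genes changed by 2-fold, 90% were called for genotype at 0 h, 82% at 4 h, 89% at 8 h and 91% at 24 h. For 4-fold changes the shares were 99%, 99%, 98% and 98%. False calls made up 7.8%, 1.09%, 7.88% and 3.57% of the calls. For the interactions, 76.1%, 75.4% and 76.5% of genes changed by 2-fold were called at 4, 8 and 24 h, and 98%, 95.4% and 97.5% of those changed by 4-fold. A list of 20 genes raised by a log2 of 0.5 at 4 h was called, as were 0.5% of the unchanged lists before adjustment. The simulated genes were drawn independently of each other. The share of false list calls therefore does not cover real lists, whose members can move together.

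Libraries at different times that share a mouse number come from the same animal per the labels, so the numbers pair the libraries within a genotype. Correlations across genes of the deviations from the group means had a median of 0.0182 over the 36 pairs of libraries from 1 mouse (−0.0846 to 0.163) and of −0.00727 over 72 pairs from different mice. No source names a block, so the main model has none, and a fit with the mouse as a replicate block was an alternative. It called 6722 genes at 4 h against 0 h in WT, where 6771 were called without the block. Within groups the correlations of the log levels of 2 libraries lay between 0.975 and 0.99, and replicates differed by more than sampling noise, with a chi-square per gene of at least 3.22.

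Alternatives were the size factors of DESeq2 (RLE), no filter, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma on log2(TPM + 1), a fit of only the groups compared, the mouse block and leaving out each mouse in turn with all its libraries. Added after seeing the data were the removal of Rn45s, leaving out the 8 h libraries of mice 2 and 5, leaving out the 4 h library of mouse 3, and the block in the list tests. Genes that share sequence with close copies, such as H2-Q9, Ly6c2, Pydc3, Tmem254c and the pseudogene Bambi-ps1, are uncertain because RSEM divides shared reads between copies. Exons were not separated in the values used, and litter, sex and day of collection are not given in the sources used here.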

Results

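TCF1, the protein encoded by Tcf7, is a transcription factor of naive and stem-like T cells. The series title names an axis of TCF1 and the chemokine receptor CXCR6 that acts on CD28 co-stimulation. The libraries compare CD8+ T cells labelled Tcf7 cKO and WT before activation and 4, 8 and 24 h after plating on antibodies against CD3 and CD28. There were 24 libraries, 3 mice for each of the 8 groups, with 5846265 to 9700397 expected counts each. Between 13694 and 17214 genes had a count, 16210 to 17214 at 0 h and 13694 to 14081 at 24 h. The ribosomal RNA gene Rn45s held 16.2 to 18.9% of counts at 0 h, 18.4 to 20.6% at 4 h, 14.2 to 17.2% at 8 h and 7.39 to 9.54% at 24 h. The first principal component held 55% of the variance and ordered the times, and the second held 26%. On the first component the 8 h libraries of mouse 2 (cKO, 24.0) and mouse 5 (WT, 25.8) lay nearer to the 24 h libraries than the other 8 h libraries, which lay between 5.14 and 14.4. The 4 h library of mouse 3 (cKO, −35.7) lay nearer to the 0 h libraries than the other 4 h libraries (−24.5 to −21.4).

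Gene-level Tcf7 RNA (chromosome 11, 52252371 to 52283014, minus strand, mm10) was not called lower in the libraries labelled cKO at 0, 4 or 8 h. At 0 h it was at 685, 681 and 719 TPM in cKO mice 1, 2 and 3 and at 567, 552 and 499 TPM in WT mice 4, 5 and 6. At 4 h the values were 263, 251 and 271 in cKO and 180, 205 and 190 in WT, and at 8 h they were 127, 73.6 and 108 in cKO and 87.4, 52.6 and 81.3 in WT. At 24 h Tcf7 was at 37.5, 35.7 and 38.3 TPM in cKO and 62.6, 77 and 68.8 TPM in WT. The log2 fold changes of cKO over WT were 0.33 (SE 0.117, adjusted p = 0.386), 0.40 (SE 0.119, adjusted p = 0.113) and 0.43 (SE 0.123, adjusted p = 0.184) at 0, 4 and 8 h. Some alternatives called Tcf7 higher in cKO, at 0 h without a filter and with only the groups compared (adjusted p over all alternatives 0.00471 to 0.746), and at 4 h with these 2 and with DESeq2 (0.00299 to 0.46). At 8 h it was called higher without a filter and without mouse 2 (0.002 to 0.806). At 24 h the value was −0.90 (SE 0.126, adjusted p = 0.000221), and this call held in all 13 alternatives, with an adjusted p of at most 0.0403. The counts cover the whole gene, including parts outside the floxed region, so they do not check whether the deletion took place. Groups are therefore named by their labels.

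**Figure D1:**
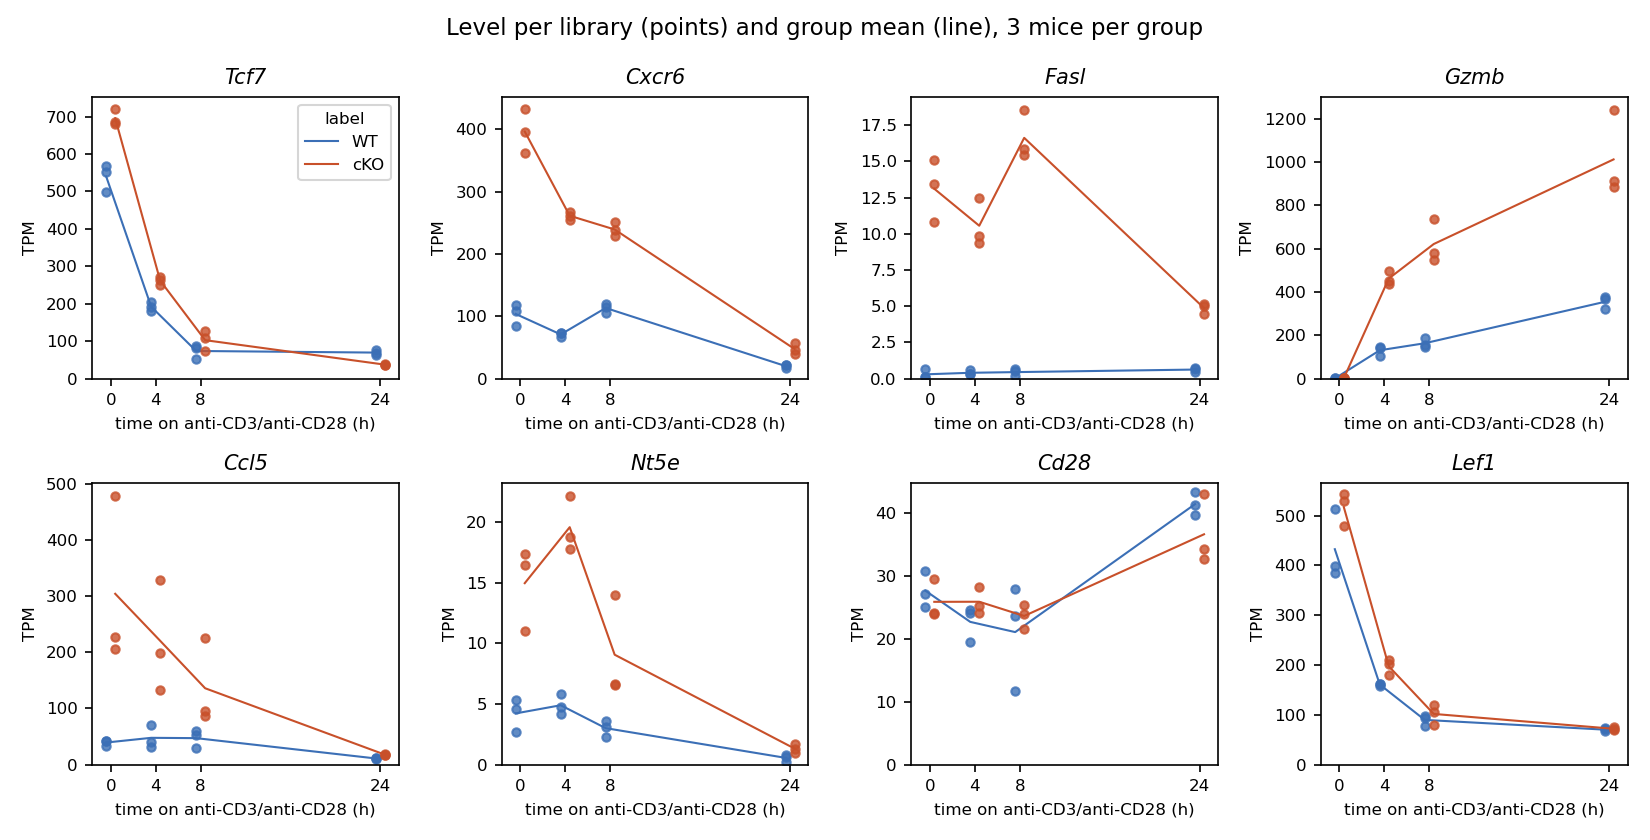
TPM of 8 genes in each of the 24 libraries (points) against hours on anti-CD3/anti-CD28 (x axis), with lines through the means of the 3 mice labelled WT (blue) and the 3 labelled cKO (red). Mean Tcf7 was at 695 TPM in cKO and 540 in WT at 0 h and at 37.2 and 69.4 at 24 h, while every cKO library lay above every WT library for Cxcr6 and Fasl at all 4 times.

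Before activation, RNAs of a chemokine receptor, a death ligand and a chemokine were higher in the libraries labelled cKO. Cxcr6 (chromosome 9, 123806475 to 123811760, plus strand) was at 396 ± 34.8 TPM in cKO and 104 ± 17.4 in WT, a log2 fold change of 1.91 (SE 0.129, adjusted p = 4.96e-11). Fasl, the ligand of the death receptor FAS (chromosome 1, 161780689 to 161788495, minus strand), was at 13.1 ± 2.15 TPM against 0.293 ± 0.292 (log2 5.44, SE 0.382, adjusted p = 2.49e-12). Ccl5, a chemokine of effector and memory T cells, was at 304 ± 152 TPM against 39.3 ± 4.64 (log2 2.91, adjusted p = 0.0071). Nt5e, an ectonucleotidase that produces adenosine, rose from 4.22 ± 1.36 TPM in WT to 15.0 ± 3.42 in cKO (log2 1.78, adjusted p = 0.00254). Further increases were those of Rgs1 (1.15), a regulator of G protein signalling, Ndrg1 (0.91), the nucleotide hydrolase Samhd1 (0.85) and the syntaxin Stx1a (0.83). Of the 15 genes called lower, 7 reached 10 TPM in the higher group without overlap between the libraries of the 2 groups, which are the limits for naming genes by size. They were Cd163l1 (−2.21, 4.91 against 22.6 TPM), Pdlim4 (−1.62, 10.4 against 31.1 TPM), the pseudogene Bambi-ps1 (−0.89), Cpm (−0.88), Mpp1 (−0.52), Slamf6 (−0.48), a receptor of naive and stem-like cells, and the AP-1 subunit Junb (−0.48). Cd86, a ligand of CD28, was at 6.40 TPM against 1.96 (log2 1.72, adjusted p = 0.00792), a call lost without mouse 1, 5 or 6 (adjusted p up to 0.147), and the integrin Itgae was at 144 against 84.5 TPM (log2 0.74). Cd28 itself was at 25.8 ± 3.18 and 27.6 ± 2.87 TPM (log2 −0.13, adjusted p = 0.95), and Lef1, the partner factor of TCF1, had a log2 fold change of 0.26 (adjusted p = 0.476).

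Of the effector and cytotoxic genes, 2 of 17 were called higher at 0 h and 0 lower (4 and 0 adjusted over the list alone), and the list as a whole was higher (camera, adjusted p = 7.1e-06, and adjusted p = 0.0426 with an estimated correlation). Apoptosis genes were higher as a list with a median log2 fold change of 0.17 (adjusted p = 0.00498, and adjusted p = 0.0464 with an estimated correlation), although 0 of 20 members were called over all genes or over the list alone. The memory-phenotype list (median 0.37, adjusted p = 0.000623) was higher with 0 of 17 members called (4 adjusted over the list alone), and this was lost with an estimated correlation (adjusted p = 0.255). The interferon-stimulated list (median 0.30, adjusted p = 0.00213, and 0.538 with an estimated correlation), the S phase list (0.19, 0.00589 and 0.389) and the adhesion list (0.13, 0.0277 and 0.314) were higher with the preset correlation alone. They had 0 of 24, 0 of 24 and 1 of 16 members called, the same adjusted over the list alone. In the naive and stem-like list 0 of 22 members were called higher and 1, Slamf6, lower (0 and 5 adjusted over the list alone). This list did not pass in the main test, while with the filter of 5 CPM it did. A study focus list, set up before the data were examined, held Cxcr6, Cd28, Cxcl16, Pdcd1, Havcr2, Cd80, Cd86, Icos and Ctla4, of which 8 were tested. In the main test at 0 h it did not pass either (2 of 8 called higher, 2 higher and 1 lower adjusted over the list alone, median −0.10). Its camera adjusted p was 0.332, and 0.52 with an estimated correlation. In all, edgeR called 51 of 11470 genes, 36 higher and 15 lower, of which 16 and 10 changed at least 2-fold. Without mouse 1, 2, 3, 4, 5 or 6 in turn it called 26, 31, 94, 21, 27 and 22 genes. Of the 15 genes named by size within the limits on level and overlap Fasl, Cxcr6 and Pdlim4 kept their calls in each case, while the other 12 lost theirs without at least 1 mouse (adjusted p up to 0.325), Ccl5 without mouse 4, 5 or 6. The interferon-stimulated list had a median of −0.03 without mouse 2 (adjusted p = 0.89).

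At 4 h granzyme RNAs had appeared in both groups and were higher in the libraries labelled cKO. Gzmb, a serine protease of cytotoxic granules (chromosome 14, 56258838 to 56262260, minus strand), was at 462 ± 31.4 TPM in cKO and 131 ± 21.0 in WT (log2 1.77, SE 0.172, adjusted p = 8.45e-06). Gzmc was at 199 ± 14.7 against 59.5 ± 6.98 TPM (log2 1.70, SE 0.188, adjusted p = 1.01e-05). Fasl (log2 4.60, SE 0.379), Cxcr6 (1.84, SE 0.131; 261 ± 6.52 against 70.8 ± 3.47 TPM), Nt5e (1.96, SE 0.284), Ccl5 (2.18, SE 0.461), the carbonic anhydrase Car2 (1.78) and Stx1a (1.08) were the other increases named by size. The cytokine Ifng was at 461 ± 54.7 against 243 ± 36.0 TPM (log2 0.88, adjusted p = 0.0335) and the chemokine Ccl3 at 4451 ± 157 against 2421 ± 388 TPM (log2 0.84, adjusted p = 0.0113). Ifng lost its call without mouse 1, 2, 3, 5 or 6 (adjusted p up to 0.198) and Ccl3 without mouse 2 or 6 (adjusted p up to 0.128). Among the decreases, Tnfsf11, the ligand RANKL, was at 11.1 ± 1.26 against 37.8 ± 15.5 TPM (−1.81), and Dusp2, a phosphatase of MAP kinases, was at 107 ± 13.2 against 362 ± 172 TPM (−1.79). In WT mice 4, 5 and 6 Dusp2 was at 186, 371 and 529 TPM and Tnfsf11 at 27.6, 30.2 and 55.6 TPM. At 8 h the order of these mice was reversed, with Dusp2 at 285, 199 and 101 TPM and Tnfsf11 at 49.3, 26.3 and 20.3 TPM. These decreases are therefore not an even step between the genotypes. Traf4 and Slc19a2, named below, had the same orders in WT at 4 and 8 h, while Ier3, Adk, Ppic and Matk did not. Ier3 (−1.10, adjusted p = 1.01e-05) and adenosine kinase, Adk (−0.98, adjusted p = 7.87e-06), were at 78.4 against 162 TPM and at 81.8 against 156 TPM. Ppic (−1.14), Matk (−1.03), Traf4 (−0.88) and the thiamine transporter Slc19a2 (−0.85) completed the 8 decreases named by size within the limits on level and overlap, out of 44 genes called lower. Cd28 (0.14, adjusted p = 0.815) and Lef1 (0.28, adjusted p = 0.23) were not called.

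Effector and cytotoxic genes had 8 of 17 members higher and 0 lower at 4 h (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.61 (camera, adjusted p = 4.51e-12, and adjusted p = 0.00447 with an estimated correlation). Fasl, Gzmb, Gzmc and Ctsw, a cathepsin of cytotoxic cells (0.50), had the smallest adjusted p, and Ctsw lost its call without mouse 5 (adjusted p = 0.0588). The study focus list, with Cxcr6 and Cd86 (1.65) called among 8 (2 adjusted over the list alone), passed with adjusted p = 0.000665. With an estimated correlation its adjusted p was 0.0299. This list includes Cxcr6 and Cd28, whose proteins the series title names, and is no independent evidence on Cxcr6. Of 24 immediate early genes, Ier3, Dusp2 and Nfkbid (−0.78) were lower and Bhlhe40 (0.51) was higher (5 lower and 2 higher adjusted over the list alone), and the list was lower (adjusted p = 0.00948, and adjusted p = 0.338 with an estimated correlation). Nfkbid lost its call in 9 of 14 alternatives (adjusted p up to 0.322) and Bhlhe40 without mouse 2, 5 or 6 (adjusted p up to 0.216). In WT mice 4, 5 and 6 Nfkbid was at 832, 1153 and 1305 TPM at 4 h. At 8 h it was at 465, 373 and 269 TPM, the reversal seen for Dusp2 and not for Ier3. The ribosome biogenesis list was lower (median −0.08, adjusted p = 0.00484, and adjusted p = 0.573 with an estimated correlation). In it Fbl (−0.52) was called among 24 (1 adjusted over the list alone), a call lost in 9 of 14 alternatives (adjusted p up to 0.255). Fbl had the same reversal in WT mice 4, 5 and 6, at 107, 122 and 151 TPM at 4 h and 215, 139 and 125 TPM at 8 h. Differences between single mice were not separated from the genotype in Dusp2, Nfkbid and Fbl. Secreted cytokines had 3 of 17 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0137, and 0.371 with an estimated correlation). The interferon-stimulated list had a median of 0.58 with 0 of 24 called (2 adjusted over the list alone; adjusted p = 1.6e-06, and 0.35 with an estimated correlation). In the naive and stem-like list Myb (−1.42) was the 1 call of 22 (1 adjusted over the list alone) and in the Wnt target list Rnf43 (1.97) the 1 call of 8 (1 higher and 1 lower adjusted over the list alone), and neither list passed. Myb lost its call in 5 of 14 alternatives (adjusted p up to 0.322), Rnf43 in 7 of 13 (up to 0.232) and Cd86 in 5 of 14 (up to 0.131). In all 94 genes were called, 50 higher and 44 lower. Without mouse 1 to 6 in turn 142, 32, 63, 156, 36 and 36 were called, of which 79, 8, 16, 109, 15 and 14 were lower. The balance of directions turned in 4 alternatives, with 91 higher and 158 lower without a filter and 100 and 116 with DESeq2 beside those without mouse 1 or 4. Without the 4 h library of mouse 3, an alternative added after seeing the data, 54 genes were called, 38 higher and 16 lower, and Tnfsf11, Dusp2, Traf4 and Slc19a2 lost their calls. Fasl, Nt5e, Cxcr6, Car2, Gzmb, Gzmc, Stx1a, Ier3 and Adk were the 9 of the 16 genes named by size that kept their calls each time. Ccl5, Tnfsf11, Dusp2, Ppic, Matk, Traf4 and Slc19a2 lost theirs at least once (adjusted p up to 0.255).

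At 8 h RNAs of the same receptor, ligand and granzymes were again higher in the libraries labelled cKO. Fasl was at 16.6 ± 1.69 TPM against 0.447 ± 0.253 (log2 5.04, SE 0.346, adjusted p = 1.28e-12) and Gzmb at 622 ± 103 against 163 ± 20.1 (log2 1.87, SE 0.171, adjusted p = 5.28e-06). Gzmc was at 314 ± 60.9 against 86.2 ± 21.1 (log2 1.83, SE 0.182, adjusted p = 4.03e-06) and Cxcr6 at 239 ± 11.9 against 113 ± 7.07 (log2 1.01, SE 0.127, adjusted p = 3.06e-05). Nrn1 (1.14), Plac8 (1.05), the interferon regulatory factor Irf7 (1.04) and Ncoa7 (0.95) were also higher. The protease inhibitor Serpine2 (−1.78; 9.37 against 30.3 TPM), the tubulin Tubb6 (−1.50) and Ier3 (−0.88) were lower. Cd28 (0.14, adjusted p = 0.806) and Lef1 (0.17, adjusted p = 0.593) were not called. Effector and cytotoxic genes had 4 of 17 higher and 0 lower (6 and 0 adjusted over the list alone; adjusted p = 5.24e-12, and 0.00447 with an estimated correlation). The study focus list had 2 of 8 higher, Cxcr6 and Cd86 (1.93), both also adjusted over the list alone (adjusted p = 0.0026, and 0.0426 with an estimated correlation). This list missed the threshold without mouse 2 (adjusted p = 0.061). Cd86 lost its call in 6 of 14 alternatives (adjusted p up to 0.189). The memory-phenotype list (median 0.31, adjusted p = 0.00118), the T cell receptor signalling list (0.13, adjusted p = 0.00176), in which Cd8a was called (0.43), and the interferon-stimulated list (0.52, adjusted p = 7.02e-09), in which Irf7 was, had 4, 5 and 6 higher and 0, 2 and 0 lower members adjusted over the list alone. With an estimated correlation their adjusted p were 0.262, 0.259 and 0.259, and Cd8a lost its call in 6 of 14 alternatives (adjusted p up to 0.202). Ribosome biogenesis (median −0.15, adjusted p = 0.00252) and cholesterol synthesis (median −0.16, adjusted p = 0.0201) were lower as lists with 0 members called, 0 and 2 adjusted over the list alone, and with an estimated correlation had adjusted p = 0.548 and adjusted p = 0.525. In all 21 genes were called, 17 higher and 4 lower, and without mouse 1 to 6 in turn 15, 32, 35, 66, 8 and 7 (adjusted p of the named genes up to 0.456). Without the 8 h libraries of mice 2 and 5, an alternative added after seeing the data, 13 were called, 9 of them shared, and Fasl, Gzmb, Gzmc and Cxcr6 kept their calls while the other 7 of the 11 named genes lost theirs.

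At 24 h 12 genes passed, with Tcf7 the 1 gene called lower. Gzmb was at 1013 ± 198 TPM in cKO and 354 ± 30.3 in WT (log2 1.52, SE 0.166, adjusted p = 9.39e-05) and Gzmc at 19.6 ± 3.31 against 5.64 ± 1.77 (log2 1.78, SE 0.276, adjusted p = 0.00272). Cxcr6 was at 47.5 ± 9.14 against 20.1 ± 3.04 (log2 1.24, SE 0.141, adjusted p = 8.3e-06) and Ifng at 274 ± 57.7 against 128 ± 21.1 (log2 1.09, SE 0.192, adjusted p = 0.0268). Dennd5a (0.69), Ctsw (0.64), the class Ib histocompatibility gene H2-Q9 (0.57) and the adhesion receptor Cd2 (0.50) were the other genes named by size. Fasl, at 4.87 ± 0.384 against 0.623 ± 0.134 TPM, was higher by a log2 of 2.96 (adjusted p = 2.43e-06). Cd28 (−0.18, adjusted p = 1) and Lef1 (0.05, adjusted p = 1) were not called. Effector and cytotoxic genes had 5 of 17 higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.60 (adjusted p = 2.37e-23, and adjusted p = 0.000293 with an estimated correlation). Secreted cytokines (1 of 17 called, 7 adjusted over the list alone; adjusted p = 2.17e-09 and, with an estimated correlation, 0.0331) and chemokine receptors (1 of 12, 2 adjusted over the list alone; 0.000353 and 0.0197) were higher with either correlation. So were the memory-phenotype list (0 of 17, 5 adjusted over the list alone, adjusted p = 6e-08 and 0.0469) and the study focus list (1 of 8, 2 adjusted over the list alone, adjusted p = 0.00194 and 0.0401). The last of these did not pass with the filter of 5 CPM (adjusted p = 0.0624).

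Other lists passed at 24 h with the preset correlation and were lost with the estimated one. Mitosis genes were lower (median −0.27, adjusted p = 0.00051, and adjusted p = 0.294 with an estimated correlation), with 0 of 20 called and 3 adjusted over the list alone. Inhibitory receptors (adjusted p = 0.0529 with an estimated correlation), interferon-stimulated genes (0.314), immediate early genes (0.227), T cell receptor signalling (0.262) and adhesion genes (0.294) were higher. These had 2, 1, 2, 3 and 2 members higher adjusted over the list alone, and 0 over all genes. In all 12 genes were called, 11 higher, and without mouse 1 to 6 in turn 9, 9, 19, 7, 6 and 9. Gzmb, Cxcr6 and Tcf7 kept their calls each time among the 9 genes named by size, while the other 6 lost theirs at least once (adjusted p up to 0.784), and a fit of the 24 h libraries alone called 100 genes, 77 higher and 23 lower. Such fits called 36, 93 and 14 genes at 0, 4 and 8 h, and Gzmb lost its 24 h call in this one (adjusted p = 0.0706).

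**Figure D2:**
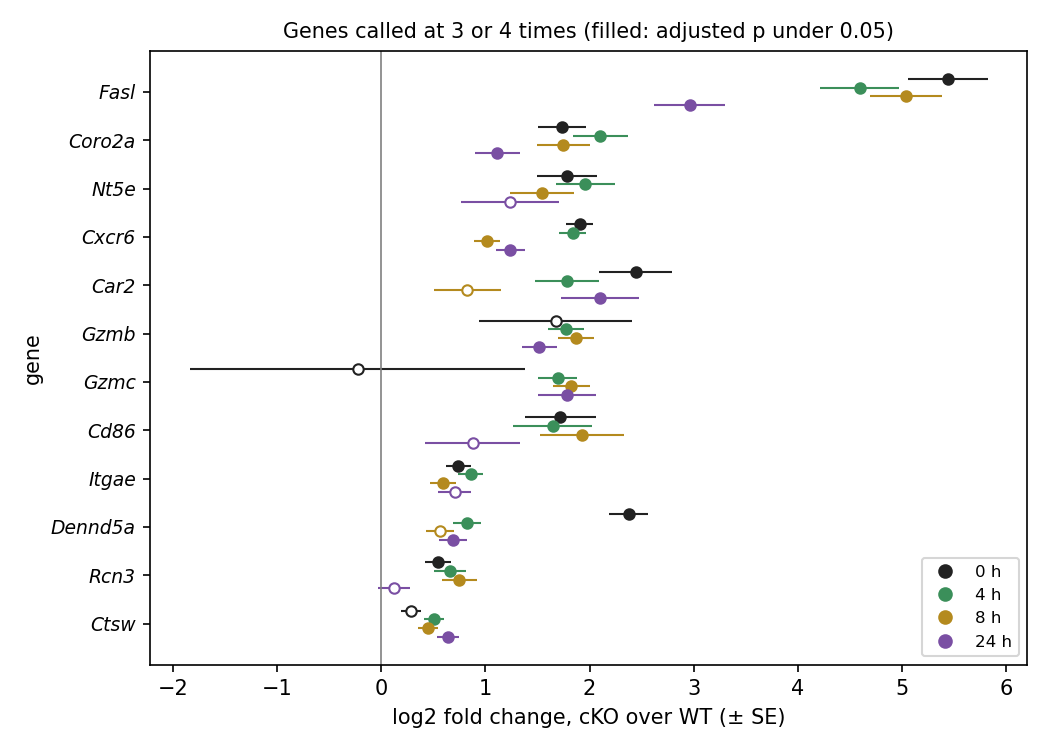
Fitted log2 fold change of cKO over WT (x axis, points) with its approximate standard error (bars) at 0, 4, 8 and 24 h for the 12 genes called at 3 or 4 times (y axis). Filled points have an adjusted p under 0.05. Cxcr6 lay at 1.91, 1.84, 1.01 and 1.24 and Fasl at 5.44, 4.60, 5.04 and 2.96.

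Over the 4 times 135 genes were called at least at 1, and 3 of them, Coro2a, Cxcr6 and Fasl, at all 4. Another 9 were called at 3 times, which were Car2, Cd86, Ctsw, Dennd5a, Gzmb, Gzmc, Itgae, Nt5e and Rcn3, and all 12 were higher in cKO where called. Cxcr6 and Fasl kept all their calls in every alternative, and each of the other 10 lost at least 1 call in at least 1 alternative. Coro2a lost its call at 24 h without mouse 1, 4 or 5 (adjusted p up to 0.18), which leaves Cxcr6 and Fasl at all 4 times. Coro2a, a coronin that binds actin, was at 6.53 ± 0.861 against 1.93 ± 0.599 TPM at 0 h and 6.84 ± 0.804 against 3.15 ± 0.3 TPM at 24 h. Of the 36 genes higher at 0 h, 15 were among the 50 higher at 4 h, where independent lists of these sizes would share 0.157. Of the 17 higher at 8 h, 13 were also higher at 4 h (0.0741 for independent lists), and of the 11 higher at 24 h, 9 were (0.048). These comparisons share no library but use the same 6 mice. By list, 10 of the 25 did not pass at any time by genotype in the main test. Their lowest camera adjusted p were 0.0707 (AP-1), 0.566 (Wnt targets), 0.161 (amino acid), 0.0739 (costimulatory receptors) and 0.0927 (glycolysis). For the rest they were 0.161 (heat shock), 0.13 (helper and regulatory), 0.284 (myeloid), 0.0739 (naive and stem-like) and 0.161 (sex-linked). Of these 10 lists only the Wnt targets passed by genotype in no alternative. Each of the others passed at some time in at least 1, such as the AP-1 list at 24 h without a filter.

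Most of the tested genes changed in WT cells after plating. Activation is used here for plating with antibodies and IL2 as a whole. No group was plated without antibody, so effects of culture, IL2 and time cannot be told apart from those of CD3 and CD28. Values are scaled within libraries, so rises and falls are relative to other genes and not per cell. After 24 h all 24 genes of the S phase list had risen and 19 of the 22 naive and stem-like genes had fallen. Both lists passed with the preset correlation and with an estimated one (adjusted p = 0.0323 and adjusted p = 0.0426). Il2 went from 1 count in the 3 libraries at 0 h to 1416 ± 56.5 TPM, a ratio of 16800 (3010 to 662000). Ccl3, with 0 counts at 0 h, was at least 5740-fold higher at 24 h, the cystathionine lyase gene Cth at least 1470-fold, Il3 at least 358-fold and the acyl-CoA synthetase gene Acsl6 at least 192-fold. The chemokines Xcl1 and Ccl4 were at 2758 ± 215 and 3391 ± 208 TPM, and asparagine synthetase, Asns, rose by a ratio of 4240 (761 to 168000). Among genes within the limits on level and overlap, the largest decreases were Cd7 (−8.30), the interferon-induced Cmpk2 (382-fold, 105 to 3160), Irf7 (−7.30), Pydc3 (−7.22) and Oasl2 (−7.12), the enzymes Ampd1 (−8.12) and Ggt1 (−7.89) and the scavenger receptor gene Cd163l1 (−7.67). Tcf7 fell by 2.91 on the log2 scale (SE 0.127), Lef1 by a log2 change of −2.68 (SE 0.109) and Cxcr6 by one of −2.32 (SE 0.141), while Cd28 rose by 0.63 (SE 0.173, adjusted p = 0.00235). In all 8828 genes were called, 4231 higher and 4597 lower.

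By list at 24 h in WT, all 24 S phase genes rose, with Rrm1, Mcm3, Mcm5 and Tk1 (6.81) named first (median 3.52, adjusted p = 5.24e-12, and adjusted p = 0.0323 with an estimated correlation). All 20 mitosis genes rose, with Cdk1 at 7.27 (median 5.84, adjusted p = 3.71e-09, and adjusted p = 0.0559 with an estimated correlation). Naive and stem-like genes fell in 19 of 22 and rose in 2, with Klf2 at −6.89 and Satb1 at −2.76 (adjusted p = 1.08e-06, and 0.0426 with an estimated correlation). T cell receptor signalling genes fell in 24 of 26, Cd8b1 by −3.24 and Cd3g by −2.37 (adjusted p = 5.53e-07, and 0.0511 with an estimated correlation), and adhesion genes in 12 of 16, Itgae by −4.48 (adjusted p = 0.00948, and 0.255 with an estimated correlation). Interferon-stimulated genes fell in 22 of 24, with a median of −4.69 (adjusted p = 9.25e-08, and 0.288 with an estimated correlation). Immediate early genes rose in 20 of 24, Il2ra by 7.62 (adjusted p = 5.46e-07, and 0.0464 with an estimated correlation), and cytokine genes in 14 of 17 (adjusted p = 4.98e-06, and 0.0825 with an estimated correlation). Ribosome biogenesis genes rose in 24 of 24, Ncl by 2.58 (adjusted p = 5.61e-11, and 0.194 with an estimated correlation), glycolysis genes in 15 of 18, Hk2 by 5.95 (5.28e-05 and 0.288). Amino acid genes rose in 19 of 20, Psat1 by 4.28 (2.78e-08 and 0.112), cholesterol synthesis genes in 14 of 19, Idi1 by 3.90 (0.0023 and 0.427), and heat shock genes in 8 of 13, Hspd1 by 3.17 (0.0468 and 0.525). Adjusted over the list alone these counts were the same, except 21 immediate early genes.

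The other lists did not pass at 24 h in WT, and their members went both ways. Effector and cytotoxic genes rose in 7 and fell in 9 of 17, Gzmb by 9.61 and Klrd1 by −5.49, with a median of −0.82 and a mean of 1.02. Rises and falls were 6 and 8 of 17 memory-phenotype genes, Cd44 by 5.62 and Il18r1 by −3.14, and 6 and 5 of 13 inhibitory receptors, Pdcd1 by 5.35 and Tox by −1.60. They were 10 and 5 of 15 costimulatory receptors, Tnfrsf4 by 6.10 and Cd2 by −3.40, and 4 and 7 of 12 chemokine receptors, Ccr4 by 3.63 and Ccr9 by −6.91. They were 7 and 4 of 16 AP-1 genes, 5 and 6 of 12 helper and regulatory genes and 10 and 7 of 20 apoptosis genes. Of 8 Wnt targets 2 rose and 3 fell, Axin2 by −2.41, and of 8 genes of the study focus list 5 rose and 2 fell. Of 3 tested myeloid and dendritic genes 1 fell, and of 5 sex-linked genes 4 fell. The camera adjusted p of these lists lay between 0.271 and 0.912. Adjusted over the list alone the counts were the same, except 6 helper and regulatory genes that rose.

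At 4 h in WT 6771 genes were called, 3437 higher and 3334 lower, and at 8 h 7726, 3827 higher and 3899 lower. Within the same limits the largest increases at 4 h were Ccl3, at least 7970-fold, Xcl1 (21700-fold, 5990 to 179000), Il2 (14500-fold, 2600 to 573000) and Ccl4 (14.25), and at 8 h Ccl3, at least 21300-fold, Xcl1 (43300-fold, 12000 to 358000), Ccl4 (14.82) and Il2 (33400-fold, 6000 to 1320000). Ampd1 (−5.62), Dtx1 (−5.46) and Slc16a5 (−4.89) fell at 4 h beside Tmem254c, a member of a multicopy family that was at least 97.8-fold lower. At 8 h Ggt1 (−6.31), Slc16a5 (−6.08), Ampd1 (−5.94) and Eya2 (−5.93) fell. Tcf7 fell by 1.40 at 4 h and by 2.74 at 8 h, Lef1 changed by −1.30 and −2.14, and Cxcr6 by −0.45 at 4 h and 0.29 at 8 h (adjusted p = 0.0488). Cd28 was not called at either time (−0.18, adjusted p = 0.387, and −0.28, adjusted p = 0.179). Immediate early genes led the lists, with 23 and 24 of 24 higher at 4 and 8 h, over all genes and over the list alone (adjusted p = 7.25e-21 and 1.27e-13, and 0.00158 and 0.00694 with an estimated correlation). Cytokine genes followed with 13 of 17 higher at both times, also over the list alone (estimated correlation, adjusted p = 0.0197 and 0.0401). All 24 ribosome biogenesis genes were already higher at 4 h (adjusted p = 1.11e-15, and 0.0825 with an estimated correlation), whereas 6 of 24 S phase genes and 1 of 20 mitosis genes were, and these 2 lists did not pass at 4 or 8 h. Apoptosis genes were higher at 4 h in 12 of 20 and lower in 4, also over the list alone (adjusted p = 0.00332, and 0.0426 with an estimated correlation).

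In the cells labelled cKO activation called 6562 genes at 4 h (3395 higher, 3167 lower), 7520 at 8 h (3801 and 3719) and 8749 at 24 h (4280 and 4469). The leading genes overlapped with those of WT. Ccl3 (0 counts at 0 h) was at least 17200-fold, 32400-fold and 10100-fold higher at the 3 times, and Il2 (0 counts) at least 4710-fold, 9740-fold and 7380-fold. Xcl1 rose by 13.99, 14.56 and 12.41 on the log2 scale, and Ccl4 was among the 4 largest increases at 4 h (13.67) and 8 h (13.84) and Asns at 24 h (5580-fold, 1000 to 221000). The largest decreases within those limits were Slc16a5 (−5.62), Ampd1 (−5.30), Dtx1 (−5.26) and Mx1 (−5.06) at 4 h, Slc16a5 (−6.06), Eya2 (−5.66), Ampd1 (−5.65) and Ggt1 (−5.50) at 8 h, and Cmpk2 (875-fold, 157 to 34600), Cd7 (−7.80), Oas2 (−7.68) and Ggt1 (−7.63) at 24 h. Tcf7 fell by 1.32 at 4 h, by 2.64 at 8 h and by 4.14 at 24 h, and Lef1 changed by −1.27, −2.23 and −2.88. Cxcr6 changed by −0.52, −0.61 and −2.98. Cd28 was not called at 4 h (0.09, adjusted p = 0.705) or 8 h (−0.01, adjusted p = 0.98) and rose by 0.58 at 24 h (adjusted p = 0.00448). Across genes, which are not independent replicates, the changes in the 2 genotypes correlated with r = 0.874, 0.915 and 0.957. Of the genes called in both, 5595 of 5600, 6696 of 6702 and 8157 of 8157 changed in the same direction.

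The interactions asked whether activation changed a gene differently in the 2 genotypes, and few genes passed. Tcf7 differed at 24 h (log2 −1.23, SE 0.171, adjusted p = 0.000411), when it had fallen further in the cells labelled cKO, and this call was lost without mouse 3 (−1.30, adjusted p = 0.0916). Dennd5a, a gene of vesicle traffic (chromosome 7, 109893780 to 109960470, minus strand), differed at 4 h (−1.56), 8 h (−1.82) and 24 h (−1.69, adjusted p = 0.000411). The 4 h call was lost with limma (adjusted p = 0.0906), with only the groups compared (0.397) and without mouse 1 (0.0713), 2 (0.12), 4 (0.109) or 5 (0.159). Its level rose from 1.65 ± 0.953 to 30.3 ± 2.99 TPM in WT and from 8.67 ± 0.947 to 55.2 ± 4.04 TPM in cKO by 4 h. These were the 1, 1 and 2 genes called, all negative, with 816, 912 and 492 genes at an unadjusted p under 0.05. With the mouse as a replicate block the counts were 2, 2 and 7, and Cxcr6 at 8 h passed with the block (−0.90, adjusted p = 0.0245) and not without it (−0.89, adjusted p = 0.101). Cxcr6 had −0.07 (adjusted p = 0.977) at 4 h and −0.66 (adjusted p = 0.45) at 24 h. Cd28 had 0.27, 0.27 and −0.05, with adjusted p of 0.884, 0.793 and 1, and Lef1 had 0.03, −0.09 and −0.21, with adjusted p of 0.987, 0.894 and 1. Tcf7 was not called at 4 h (0.07, adjusted p = 0.977) or 8 h (0.10, adjusted p = 0.904). Cytokine genes were more induced in cKO at 4 h (median 0.28, adjusted p = 0.00179) and 24 h (median 0.36, adjusted p = 1.77e-06) with the preset correlation, with 0 of 17 called and 2 and 3 adjusted over the list alone. With an estimated correlation their adjusted p were 0.262 and 0.0695. The other 9 list calls among the interactions had an adjusted p of 0.264 or more with an estimated correlation.

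Markers of other cell types were low in all groups. B cell markers had a median of 0.04 to 0.227 TPM per group, with Cd79b the highest at 48 TPM in cKO and 33.5 TPM in WT at 0 h. Natural killer cell markers had medians of 0 to 0.183 TPM, with a highest value of 1.75 TPM for Tyrobp in cKO at 0 h and 0.95 TPM in WT. Of 16 myeloid markers only Cst3 exceeded 5 TPM in any group (95.8 to 168 TPM), and of 10 stromal and endothelial markers only Pecam1 did (3.34 to 64.2 TPM). Erythroid and platelet markers reached 7.32 TPM for Hba-a1 in cKO at 4 h, and at most 0.247 TPM in WT at that time. The sex-linked list did not pass by genotype at any time in the main test, with 0 of 5 members called, while it passed at 4 h without mouse 1. It holds Xist as well as Y-linked genes, so a test for 1 direction cannot show whether the sexes match. Mean Eif2s3y, a Y-linked gene, was at 71.0 to 89.6 TPM in every group.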

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

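The tests in this part were chosen, and their predictions written, after the results had been seen, and the rule for the slopes was changed 2 times after their values had been seen. Gene-level Tcf7 was not lower in the libraries labelled cKO before 24 h and differed from that at 24 h (interaction −1.23, SE 0.171, adjusted p = 0.000411), which a difference between the groups flagged. An exchange of the genotype labels between the times is excluded as far as this test goes, since at least 81.8% of the other genes called at 24 h had the same sign at each earlier time. No alternative, RLE size factors, TPM and removal of Rn45s included, gave a negative log2 fold change before 24 h. The lowest was 0.281 at 0 h over 13 alternatives, and 0.379 at 4 h and 0.252 at 8 h over 14. All these scalings set a gene against the others of its library, so a difference in total RNA per cell could not be tested. Transcripts of a deleted allele that lack the deleted part may still be counted. The files give 1 length for Tcf7 in all libraries, which leaves this open, and no value here tells a lack of deletion from a deletion that leaves the RNA.

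Cytotoxic genes and Cxcr6 were higher in the libraries labelled cKO, and a larger share of memory-like cells in those mice could bring this. Ly6c2, a marker of such cells that shares reads with a close copy, was at 1107 ± 540 TPM in cKO and 311 ± 70.8 TPM in WT at 0 h (log2 1.80, adjusted p = 0.27). Extra cells of 1 kind, with the same content in each mouse, would give TPM excesses over WT that follow that of Ly6c2 with a log2 slope near 1, and over the means of the 3 cKO mice the slopes were 0.179 for Cxcr6 (95% interval 0.0427 to 0.314) and 0.0117 for Fasl (−0.173 to 0.196). The slopes for these 2 genes lay under 1, but they rest on 3 mice and 1 marker, and error in Ly6c2 would lower them. For Ccl5 the slope was 0.61 (−1.9 to 3.12). Cells whose content differs between mice were not tested. A larger share of memory-like cells therefore remains open for Cxcr6, Fasl and Ccl5. Natural killer cells do not account for Ccl5, since their 9 markers summed to 1.16 TPM more in cKO and Ccl5 was 265 TPM higher.

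Other results were marked by a called interaction or by libraries that parted in opposite directions at 2 times in TMM-scaled CPM. The libraries of 6 of the 56 genes examined did so. Of the 6, Tcf7 is given above, and Junb and Tnfrsf1b were dropped after their values had been seen. Their opposite times include 0 h, for which the interactions test the difference, and these had an adjusted p of at least 0.0734 and 0.435. For Dennd5a the genotype difference on the log2 scale was smaller at each later time than at 0 h. The interactions were −1.56 (SE 0.235, adjusted p = 0.00224) at 4 h, −1.82 (SE 0.236, adjusted p = 0.000113) at 8 h and −1.69 (SE 0.237, adjusted p = 0.000411) at 24 h. Its WT level at 0 h was low (1.21, 0.99 and 2.74 TPM in mice 4, 5 and 6). In TPM the group means lay further apart at each later time than at 0 h. Dusp2 was at −1.79 at 4 h (adjusted p = 0.0188) and 0.779 at 8 h (adjusted p = 0.44), and Matk at −1.03 at 4 h (adjusted p = 0.00789) and 1.15 at 24 h (adjusted p = 0.624). Traf4 was at −0.879 at 4 h (adjusted p = 0.033) and 0.455 at 8 h (adjusted p = 0.437). In TPM its 8 h libraries overlapped, at 33.7, 37.2 and 41.4 in cKO and 34.1, 26.2 and 19.1 in WT. The differences between those times were not tested.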

How the results depend on the processing

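The alternatives without Rn45s, without the 8 h libraries of mice 2 and 5, without the 4 h library of mouse 3, and with the mouse block in the list tests were chosen after the results had been seen. Cxcr6 and Fasl kept their calls by genotype at all 4 times in every alternative, with Cxcr6 between 1.78 and 2.02 at 0 h, 1.80 and 1.88 at 4 h, 0.90 and 1.12 at 8 h and 1.08 and 1.33 at 24 h. Fasl ranged more widely, from 3.46 to 6.59, 3.04 to 5.10, 3.62 to 5.41 and 1.86 to 3.09, with the lowest at each time from limma on log2(TPM + 1), where the added 1 lowers folds of genes with few TPM. The counts for time kept within 1.5 times of 6771, 7726 and 8828 in WT and 6562, 7520 and 8749 in cKO. By genotype at 0 h (51 genes) 136 were called without a filter and 84 with DESeq2, and leaving out 1 mouse gave 21 to 94. At 4 h (94) the values were 249, 216 and 32 to 156, with 54 without the 4 h library of mouse 3. At 8 h (21) they were 135, 67 and 7 to 66, with 33 under the filter of 5 CPM, 32 with limma and 13 without the 8 h libraries of mice 2 and 5. At 24 h (12) they were 32, 27 and 6 to 19, with 100 for only the groups compared. The interaction at 4 h (1) gave 45 without a filter, 5 with DESeq2, 5 with limma, 0 with only the groups compared, 2 with the replicate block and 0 to 2 without 1 mouse. At 8 h (1) it gave 34, 14, 2 with limma, 2 with the block and 1 to 4. At 24 h (2) it gave 21, 8, 4 with limma, 7 with only the groups compared, 7 with the block and 2 to 5. With the block in the list tests the heat shock list at 24 h in WT was lost (adjusted p = 0.0508) and the naive and stem-like list in the 24 h interaction was gained (adjusted p = 0.0485). The direction of the list test turned in 3 results. The interferon-stimulated list at 0 h had a median of −0.03 without mouse 2 (adjusted p = 0.89), in a range of −0.03 to 0.507. Wnt targets at 24 h in WT (median −0.749) were up in fry (adjusted p = 0.00335) and not called by camera (adjusted p = 0.806). The heat shock list in the 24 h interaction was at −0.15 without mouse 6 (adjusted p = 0.0408), in a range of −0.15 to 0.148. The median alone changed sign, with the direction of the test kept, in 3 other lists that had passed. These included the S phase list at 0 h without mouse 1 (−0.000177, adjusted p = 0.424) and the study focus list at 24 h with the filter of 5 CPM (−0.0217, adjusted p = 0.0624). The remaining one was the interferon-stimulated list in the 8 h interaction without mouse 1 (−0.0809, adjusted p = 0.834). Leaving out mice leaves fewer samples, and for the other changes the cause was not tested. Without a filter the median log2 fold change of all genes at 24 h in WT went from −0.0838 to −0.527. With depths of 5846265 to 9700397 counts, genes of low level are limited most.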

Other observations

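Of the tests in this part, the 2 on the 8 h split were written before their values were seen and after the split itself had been. Ly6a, Eomes and Ly6c2, genes of memory-like cells named after their values were seen, were not called by genotype at any time in the main test and varied between the mice labelled cKO. Some alternatives called them. Ly6c2 was called without mouse 3 at all 4 times, with DESeq2 at 4, 8 and 24 h, with limma at 8 and 24 h and without mouse 1 at 24 h (adjusted p down to 2.08e-07). Ly6a was called without mouse 3 at 0, 4 and 24 h (adjusted p down to 0.000221) and with only the groups compared at 4 and 8 h, and Eomes without a filter at 8 and 24 h and with DESeq2 and only the groups compared at 8 h (adjusted p down to 0.000115). At 0 h Ly6a was at 277, 424 and 82.0 TPM in mice 1, 2 and 3 and at 131, 98.5 and 122 TPM in mice 4, 5 and 6. Ly6c2 was at 1625, 1149 and 548 TPM in cKO and at 258, 283 and 392 TPM in WT, and at 24 h at 334, 115 and 91.5 TPM in cKO and 13.1, 13.3 and 17.9 TPM in WT (log2 3.60, adjusted p = 0.0583). Eomes was at 9.27, 3.12 and 6.30 TPM in cKO at 0 h and at 3.77, 4.26 and 3.67 TPM in WT.

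Each comparison was also run over 10 splits into 3 and 3, the real one included, of the mice or, for time, of the 6 libraries, and 10 splits cannot give a share under 0.05. By genotype the real count and the highest other were 51 and 6 at 0 h, 94 and 8 at 4 h, 21 and 648 at 8 h and 12 and 1 at 24 h. Counting the real split, 1, 1, 2 and 1 splits called as many. For time in WT they were 6771 and 0, 7726 and 0, and 8828 and 0, and in cKO 6562 and 30, 7520 and 2, and 8749 and 1, with 1 split each calling as many. Every other split for time mixes 0 h with later libraries in both of its groups. This widens the spread of genes that change over time, so low counts follow from the design and do not test the real count. Of these splits of libraries, 3 part all 3 pairs from the same mouse as the real one does, and the others part 1 pair. The highest of those 3 called 0, 0 and 0 genes in WT and 30, 2 and 0 in cKO, and the real one with the mouse as a replicate block called 6722, 7687 and 8808 in WT and 6511, 7519 and 8719 in cKO. For the interactions the real count and the highest other were 1 and 4, 1 and 1, and 2 and 0, with 2, 3 and 1 splits calling as many.

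At 8 h the split of mice 1, 3 and 4 against 2, 5 and 6 called 648 genes where the genotypes called 21, which points to a structure of the 8 h libraries that crosses the genotypes. Libraries of mice 2, 5 and 6 further along the course of activation may account for it, since 84% of the 648 genes (544) differed in the direction of the change from 4 h to 24 h, against 62.7% of all genes. On the first principal component, however, mouse 6 (14.4) lay near mouse 4 (13.2), which is on the other side of the split. Mice 2 (24.0) and 5 (25.8) alone stood apart. Greater depth in the libraries of mice 2, 5 and 6 does not account for the whole of the structure, since after thinning to the smallest total the split still called 466 genes and the genotypes 18. Of the 466, 446 were among the 648 (68.8%), which lies between the bounds set for this test, so depth as a part of it remains open.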
